A study of Mus musculus with 10 samples.

How the data were processed

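Livers of wild-type C57BL/6 mice were dissociated at 5 postnatal ages, and 10 libraries were made with the 10x Chromium 3' single-cell chemistry, per the labels' protocols. Neonatal livers (D1, D3 and D7) were dissociated mechanically and enzymatically without perfusion, and hepatocytes and non-parenchymal cells were separated by centrifugation and mixed again by cell number. Livers at D21 and D56, from 2 male mice at each age, were perfused, hepatocytes were purified over Percoll, and dead cells were removed from the non-parenchymal cells. Red cells were lysed in all non-parenchymal preparations. Whether each neonatal library was a separate animal, and whether the 2 mice of a later age were pooled, is not given in the sources used here.

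The deposited metadata give UMI counts per cell as whole numbers, which the authors did not normalize as far as the file shows. The deposited mitochondrial values are a percent of each cell's UMIs, and multiplied by the UMI count they gave whole numbers in 100% of cells (tolerance 1e-06). Reads were processed with Cell Ranger 3.0.2 on the GRCm38 build, per the submitters' processing notes. Steps after that, such as doublet removal, batch correction and clustering, are not given in the sources used here, and no doublet caller was run, since that needs values per gene. The deposited lists held 65891 barcodes, of which 52834 were in the metadata and 13057 were not. The metadata held no cell under 500 UMIs, under 201 genes or over 9.99% mitochondrial UMIs, and the library number of each cell matched its barcode in 52834 cells. A list of genes without values was not used.

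Cell types are the authors' deposited labels, 31 in all. The 3 hepatocyte labels are named by age and were merged, giving 29 types, 28 of them non-hepatocyte. Abbreviated labels are not spelled out in the sources used here. They were placed in 5 lineage groups by their usual reading, fixed as groups before the data were examined; HSC can be read in more than 1 way and was placed with stromal cells.

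Titles number the libraries of each age 1 and 2, and the design took them as replicates. The deposited library names at D21 and D56 showed a hepatocyte and a non-parenchymal fraction instead. The fits were kept as designed, over 10 libraries, and repeated without the hepatocyte fractions, with the fractions summed and without D21. These alternatives were chosen after the data were seen. The fit without the hepatocyte fractions is named below as the non-parenchymal (NPC) libraries alone. Its neonatal libraries still held both fractions mixed, so it did not match the fraction. Whether same-numbered neonatal libraries deviate together was checked by the correlation of their deviations over types: for UMIs per cell it was 0.583 (D1 and D3), 0.212 (D1 and D7) and 0.261 (D3 and D7) over 15 types, so the fit with the replicate number as a block is given beside that result; this check was made after the blocked counts had been seen, and the labels do not say what the numbers share. Shares of single libraries at D21 and D56 carry exact binomial 95% intervals, which cover counting error only, and a count of 0 was given a floor of 3 cells of that library. Folds set these shares against the mean of the 6 neonatal libraries.

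Cells were counted per type and library, since cells are not replicates. Shares were tested with edgeR 4.0.16 (quasi-likelihood F-test, age as a factor, total cells as offset, no TMM factors), for types with at least 10 cells in total, with Benjamini-Hochberg adjustment over types and a threshold of 0.05. The SE given with an edgeR log2 change is the size of that change divided by the square root of its F value. It restates the test and is not a separate estimate of error. Alternatives were TMM factors, no filter, at least 100 cells per type, DESeq2 1.42.0, limma 3.58.1 on log2 shares with 0.5 cells added, each library left out in turn, the replicate number as a block, removal of erythroid cells, and cells with at least 1000 UMIs. Stages within the erythroid, B and NP lineages were tested with the lineage's cells as offset in the libraries with at least 20 cells of each lineage. Medians per type and library, over at least 20 cells, of UMIs, of genes within 0.8 to 1.25 times the type's median UMI count and of the mitochondrial percentage (log2 after adding 0.1) were tested with limma for types with a median in at least 8 libraries. Thinning cells to an equal depth needs values per gene and was not done. Composition distances were Bray-Curtis distances tested by exact permutation over all pairings, and the barcodes kept were compared by exact permutation over 210 splits, with Wilson intervals per library.

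The types named in full are the 10 with the smallest p in the omnibus test of non-hepatocytes; the others are given as counts or single values, as all members of the lineage groups were to be named. Megakaryocyte and EC are also given with values at each age, as are Kupffer cells at the neonatal ages, a choice made after their values were seen. Dcn+ Mac, Cholangiocyte and the Kupffer values per fraction were singled out after their values were seen. The F-test over ages was checked on simulated counts with known changes before use. For rises at D21 and D56 against neonatal libraries in a fit of 10 libraries, it called 98.8% of types changed 8-fold, 69.6% of those changed 4-fold and 6.2% of those changed 2-fold. The dispersion was 0.259, below the 0.522 of the fit to the 10 libraries. Only rises in 6 types were simulated, with library totals held fixed. Falls, the pull of shares on each other and the calls of single contrasts were not checked. R 4.3.3, Python 3.11.15 and SciPy 1.17.1 were used.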

Results

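Single cells from the livers of wild-type C57BL/6 mice were profiled by droplet-based 3' single-cell RNA sequencing at postnatal days 1, 3, 7, 21 and 56 (D1, D3, D7, D21 and D56), with 2 libraries at each of 5 ages. The per-cell values comprised the UMI count, the number of detected genes, the mitochondrial percentage and the authors' cell type label for 52834 cells, and levels of single genes were not analysed here. Libraries held between 1272 and 9309 cells, total counts from 3274126 to 50436485 UMIs, and medians from 1164 to 7012.5 UMIs per cell. Both libraries of D1, D3 and D7 were made by the same protocol. At D21 and D56 the deposited library names showed that replicate 1 was a hepatocyte fraction (H) and replicate 2 a non-parenchymal fraction (NPC), so each fraction of these ages was measured once. Whether the H and NPC libraries of an age came from the same mice is not given. The fits over 10 libraries count them as independent replicates. As different fractions they are not replicates of an age, even if the mice were separate, so the spread in these fits includes the difference between fractions. The p-values and SEs of these fits carry that limit and also assume independent libraries. The common dispersion of non-hepatocytes was 0.522 over 10 libraries and 0.252 without the H libraries. Nothing in the labels says that the neonatal libraries came from separate animals, and p-values measure only the spread between these libraries.

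The first question was how the make-up of the non-hepatocyte cells changed over postnatal life. The blood-forming groups shrank and T cells expanded. Erythroid cells, megakaryocytes and progenitors together made up 35.4% ± 6.77 of non-hepatocytes at D1, 34.4% ± 11.2 at D3 and 14.8% ± 2.75 at D7 (SD, n = 2 each), against 2.42% in the D21 NPC library and 0.395% in the D56 NPC library. Lymphoid cells made up 18.8% ± 1.30, 21.9% ± 9.39 and 24.4% ± 3.75 at the neonatal ages, 76.3% in the D21 NPC library and 38.5% in the D56 NPC library. Stromal and epithelial cells made up 4.51% ± 1.27, 6.24% ± 0.249 and 15.1% ± 0.0137, then 3.13% and 45.4%, and myeloid cells 41.3% ± 9.34, 37.5% ± 2.08 and 45.6% ± 1.02, then 18.1% and 15.7%. The H libraries of D21 and D56 differed from these: 8.33% and 10.6% lymphoid, 36.4% and 49.7% myeloid, 54.5% and 39.7% stromal and epithelial, and 0.758% and 0% in the erythroid group. The authors kept 55.4% of the barcodes of the D21 NPC library, and whether the removed barcodes would change its shares was not tested.

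**Figure D1:**
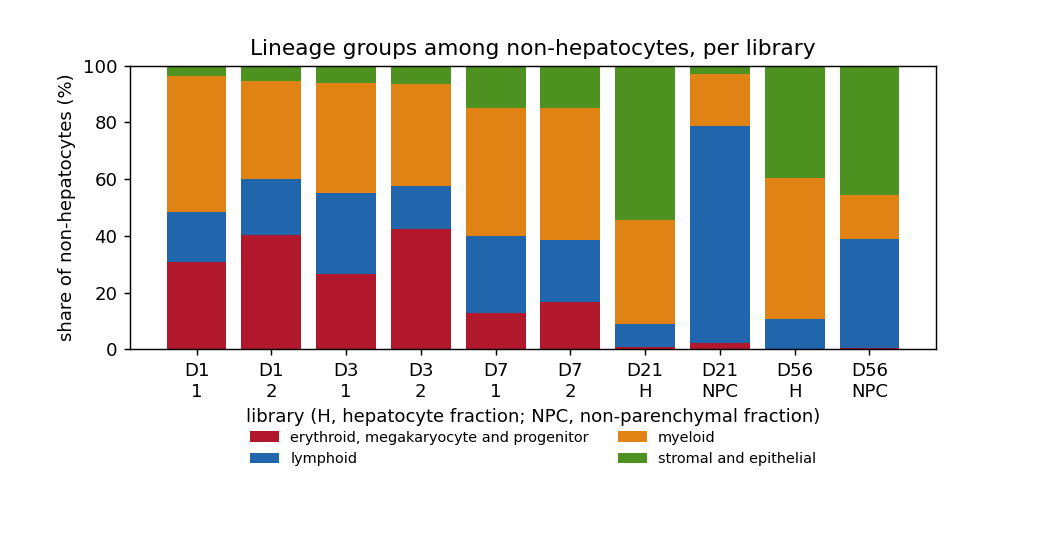
Stacked bars give the share of non-hepatocytes (%, vertical axis) in 4 lineage groups for each of the 10 libraries (horizontal axis), with the D21 and D56 libraries marked as hepatocyte (H) or non-parenchymal (NPC) fraction. The erythroid, megakaryocyte and progenitor group lies between 12.9% and 42.3% in the neonatal libraries and at or below 2.42% in the later ones.

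Across the 5 ages, 18 of 28 non-hepatocyte types differed in share (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05, 10 libraries), and the contrast of D21 and D56 with D1, D3 and D7 called 18 types, of which 6 rose and 12 fell. All 6 members of the erythroid, megakaryocyte and progenitor group fell (6 adjusted over the list alone). Of the 6 lymphoid members, T and NK rose, Pro-B, Large Pre-B and Small Pre-B, the precursor stages of B cells, fell, and B did not pass (5 adjusted over the list alone). Of the 11 myeloid members, cDC2, pDC and aDC rose, iNP and imNP fell and 6 did not pass (5 adjusted over the list alone). Of the 5 stromal and epithelial members, EC rose, Fibroblast fell and 3 did not pass (2 adjusted over the list alone, and 0 of 5 in the NPC libraries alone). With TMM factors in place of total cells, 3 types rose and 12 fell. Without the H libraries, all 18 types called in the fit of 10 libraries kept the same sign. That fit assumed that the lone libraries of D21 and D56 vary like the neonatal ones. Its neonatal libraries held both fractions mixed, so it did not match the fraction. The contrast of later with neonatal ages cannot be told apart from the dissociation protocol, which changed between D7 and D21. Shares that sum to 100% also move against each other.

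The falling types reached very low shares at D56. Pro-erythroblasts, the earliest labelled erythroid stage, made up 15.6% ± 2.49 at D1, 7.47% ± 0.647 at D3 and 4.18% ± 4.07 at D7 (SD, n = 2 each), 0.101% in the D21 NPC library (3 of 2971 cells) and 0.0382% in the D56 NPC library (3 of 7851 cells). The D56 share was 238-fold lower than the mean of the 6 neonatal libraries, with an exact binomial 95% counting interval of 81.4 to 1154, and the log2 change of later against neonatal libraries was -7.07 ± 1.07 (SE, adjusted p = 3.48e-05). Both NPC libraries lay below the lowest neonatal library, while the H libraries held 0 of 264 and 0 of 151 non-hepatocytes, too few cells to place them. Erythroblasts made up 10.2% ± 5.63, 16.6% ± 12.2 and 6.66% ± 1.03 at the neonatal ages, then 0.370% and 0.191%, a log2 change of -5.58 ± 0.94 (adjusted p = 6.98e-05). Erythrocytes made up 4.90% ± 4.23, 6.94% ± 2.34 and 1.97% ± 0.934, then 0.942% and 0.0509%, although red cells were lysed during preparation at all ages. GMP made up 2.13% ± 0.630, 1.32% ± 0.170 and 0.704% ± 0.427, then 0.337% and 1 of 7851 cells, which was 109-fold lower than the neonatal mean (counting interval 19.5 to 4293). Megakaryocytes, which form platelets, made up 0.556% ± 0.0351, 0.567% ± 0.0777 and 0.456% ± 0.0492, then 0.135% and 0 of 7851 cells, at least 13.8-fold lower than the neonatal mean at a floor of 3 cells in that library. HPC fell by 2.82 on the log2 scale (adjusted p = 0.00559).

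Among myeloid cells, imNP made up 23.8% ± 3.65, 14.1% ± 2.93 and 18.4% ± 2.35 at D1, D3 and D7 (SD, n = 2 each), 1.78% in the D21 NPC library and 2 of 7851 cells in the D56 NPC library. This was 737-fold lower than the neonatal mean (counting interval 204 to 6085), with a log2 change of -6.73 ± 1.04 (adjusted p = 3.48e-05). iNP made up 4.36% ± 0.699, 4.62% ± 2.49 and 1.48% ± 0.106, then 0.505% and 0 of 7851 cells, at least 91.3-fold lower than the neonatal mean. cDC2 went the other way, from 0.0281% ± 0.0189 at D1 through 0.152% ± 0.00850 and 0.363% ± 0.198 to 0.606% and 3.29%. The cDC2 share was 18.2-fold higher at D56 than the neonatal mean (counting interval 16.0 to 20.5), with a log2 change of 4.11 ± 0.79 (adjusted p = 0.000202). That call ended without D21 replicate 2 (log2 change 0.47, adjusted p = 0.966), since the D21 H library held 0 cDC2 among 264 non-hepatocytes, with an exact 95% upper limit of 1.39%. pDC rose by a log2 change of 2.92 ± 0.68 (adjusted p = 0.000836). The aDC call (log2 change 2.54 ± 0.94, adjusted p = 0.0234) ended with TMM factors, without D1 replicate 2, D3 replicate 2 or D56 replicate 2 and without both D21 libraries, and without D21 replicate 2 the change was -1.04.

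T cells made up 0.210% ± 0.172 of non-hepatocytes at D1, 1.04% ± 1.07 at D3 and 3.70% ± 1.63 at D7 (SD, n = 2 each), 37.0% in the D21 NPC library (exact 95% interval 35.3% to 38.8%) and 22.0% in the D56 NPC library (21.1% to 23.0%). Their log2 change was 4.30 ± 0.79 (adjusted p = 0.000122), and both NPC libraries lay above the highest neonatal one. NK cells made up 24.7% of the D21 NPC library and 5.85% of the D56 NPC library, 9.42-fold and 2.23-fold above the neonatal mean of 2.63%. In the H libraries, which enter the same fit, NK numbered 5 of 264 non-hepatocytes at D21 and 3 of 151 at D56. The NK call (log2 change 1.68 ± 0.70, adjusted p = 0.0407) ended with TMM factors, with limma, with the replicate number as a block, without both D21 libraries, and without D1 replicate 2, either library of D3 or D7, D21 replicate 2 or D56 replicate 2, each left out alone. Pro-B made up 1.42% ± 1.19, 1.05% ± 0.0223 and 6.19% ± 2.41, then 1.21% and 0 of 7851 cells, at least 75.6-fold lower than the neonatal mean. Large Pre-B made up 5.98% ± 3.46, 3.82% ± 0.217 and 4.35% ± 3.10, then 2.36% and 1 of 7851 cells, 370-fold lower than the neonatal mean (counting interval 66.5 to 14621). Small Pre-B fell by 3.78 on the log2 scale (edgeR adjusted p = 0.00166), with 89 of 2971 cells in the D21 NPC library and 6 of 7851 at D56. In the D21 NPC library Pro-B, Large Pre-B and Small Pre-B all lay within the range of the neonatal libraries. Their falls thus rest on the D56 NPC library and on 0 cells among the few non-hepatocytes of the H libraries.

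**Figure D2:**
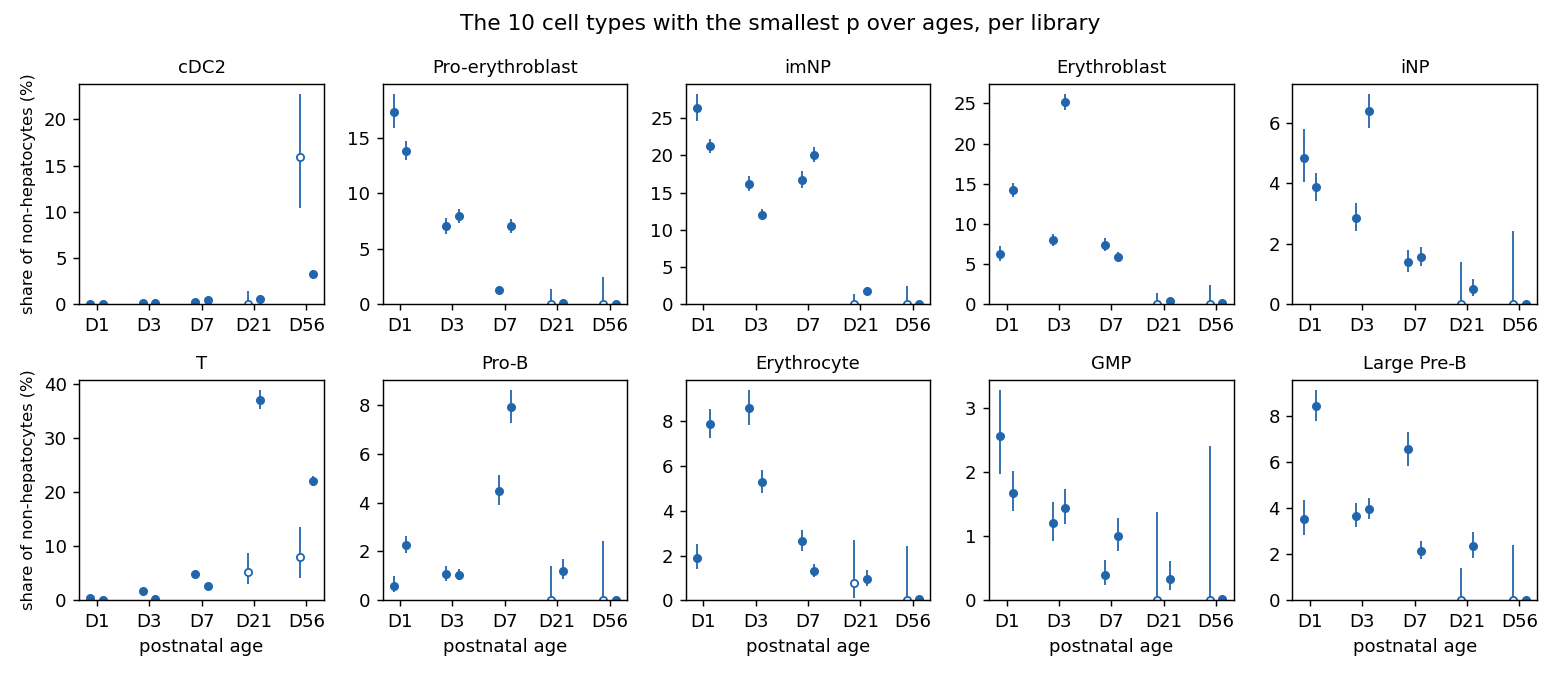
Each panel gives the share of non-hepatocytes (%, vertical axis) of 1 of the 10 types with the smallest omnibus p by postnatal age (horizontal axis); points are libraries, open points hepatocyte fractions, and bars exact 95% binomial intervals for counting error. T rises from 0.210% at D1 to 37.0% in the D21 NPC library, and imNP falls from 23.8% to 2 of 7851 cells.

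EC made up 2.90% ± 0.241, 4.03% ± 0.323 and 10.1% ± 2.61 of non-hepatocytes at D1, D3 and D7 (SD, n = 2 each), 2.29% in the D21 NPC library and 43.1% in the D56 NPC library. In the H libraries they numbered 129 of 264 non-hepatocytes at D21 and 50 of 151 at D56. Their median mitochondrial share at D21 was 5.37% (H) and 2.73% (NPC), against 1.02% to 1.69% in neonatal libraries, and whether cell quality bears on their share was not tested. Their log2 change was 2.66 ± 0.72 over 10 libraries (edgeR adjusted p = 0.00263), a call that ended with TMM factors and with limma. Without the H libraries it was 1.02, against neonatal libraries that held both fractions. Fibroblast fell by 3.59 on the log2 scale (adjusted p = 0.00507), a call that ended without both D21 libraries. Kupffer cells, the resident macrophages of the liver, depended on the fraction. They made up 1.28% of the D21 NPC library and 3.59% of the D56 NPC library but 29.2% and 9.93% of the non-hepatocytes in the H libraries, against a neonatal mean of 8.50%. Their log2 change was 0.29 ± 0.74 over 10 libraries (edgeR adjusted p = 0.755). Without the H libraries it was -1.91, against neonatal libraries that held both fractions. Dcn+ Mac and HSC also changed sign between these fits, from 1.97 to -2.76 and from 1.19 to -1.87, without passing the test in either.

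Between neighbouring ages fewer types passed. From D7 to D21, 4 types fell (Pro-erythroblast, imNP, Erythroblast and Fibroblast) and 0 rose. In the NPC libraries alone 2 types rose (pDC, adjusted p = 0.0263, and NK, adjusted p = 0.0270, edgeR) and 4 fell (imNP, Kupffer, Pro-erythroblast and Erythroblast), with the fractions summed pDC and NK rose and imNP fell, and with the H library as the only D21 library 1 type rose and 5 fell. Over 10 libraries the count of 4 was 2 without D7 replicate 1, 0 without D7 replicate 2 and 8 without D21 replicate 1. From D21 to D56, cDC2 and Cholangiocyte rose and imNP, iNP, Pro-B, Erythrocyte, Large Pre-B and Small Pre-B fell. With TMM factors 0 rose and 6 fell, and with limma 2 rose and 0 fell. The count of 8 became 0 without D21 replicate 2, 1 without D56 replicate 2, 5 without D56 replicate 1 and 14 without D21 replicate 1. Between D1 and D56, 7 types rose and 11 fell, and with TMM factors 2 rose and 11 fell. Leaving out D56 replicate 2 cut the calls between D1 and D56 from 18 to 7, those of the omnibus test from 18 to 10, and those of the later against the neonatal ages from 18 to 12. Of the types named here, Fibroblast, GMP, HPC, Megakaryocyte, Pro-B, NK and aDC lost that last call. Sizes of calls that stayed depended on D21 replicate 2: without it the log2 change was -8.41 in Small Pre-B, -6.37 in HPC, -9.48 in Large Pre-B, -7.60 in GMP, -9.58 in Pro-B, -5.93 in Fibroblast, -11.04 in imNP, -10.13 in iNP, -8.88 in Erythroblast, -7.57 in Megakaryocyte and 1.76 in pDC. Without D21 replicate 1 it was 0.93 in EC, and without D56 replicate 2 it was -6.05 in Small Pre-B and -8.45 in Erythroblast.

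Within the neonatal protocol, the shares of several immune and endothelial types were higher at D7 than at D1, but none passed the adjusted threshold with edgeR. The F-test over D1, D3 and D7 called 0 of 28 types, with 8 at an unadjusted p under 0.05 (cDC2, cDC1, EC, pDC, Pro-B, aDC, T and Dcn+ Mac, adjusted p = 0.0875 each). DESeq2 called 5 and limma 0. For D7 against D1 edgeR called 0, with 13 at an unadjusted p under 0.05, whereas DESeq2 called 7, all higher at D7, and limma 5, all higher at D7. EC gave a log2 difference of 1.80 ± 0.46 and cDC1 of 1.95 ± 0.47 (adjusted p = 0.0549 each), with both D7 libraries above all D1 and D3 libraries for EC. Without D1 replicate 1 the F-test called 5 types, and without D1 replicate 2 it called 4. In simulated data with rises at D7 against D1 and D3 together, with 6 neonatal libraries, the F-test over ages called 91.7% of types changed 8-fold. It called 37.9% of those changed 4-fold and 5% of those changed 2-fold.

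Stages within a lineage were compared to ask whether maturity shifted apart from the size of the lineage. In the NP group, mNP made up 37.0% of 108 cells in the D21 NPC library and 94.9% of 39 cells in the D56 NPC library, against 1.39% to 9.56% in the 6 neonatal libraries. The mNP median in the D56 NPC library was 603 UMIs, close to its lowest kept cell at 500, against 1251 to 2219 in neonatal libraries. Whether a UMI minimum lowered the mNP share there was not tested. Among all non-hepatocytes imNP and iNP fell, and mNP did not rise (log2 change of later against neonatal libraries -1.49 ± 0.84). Its log2 change within the group was 3.17 ± 0.65, and that of imNP -2.30 ± 0.51 (edgeR adjusted p = 0.00697 each), while iNP did not pass (-4.96 ± 1.79, adjusted p = 0.0509). In the B lineage, the label B made up 99.2% of 836 cells in the D56 NPC library and 54.9% of 432 cells in the D21 NPC library, against 5.70% to 43.1% at the neonatal ages, but its change within the lineage did not pass (log2 change 1.47 ± 0.68, edgeR adjusted p = 0.102). Pro-B fell by 5.15, Large Pre-B by 4.19 and Small Pre-B by 2.82 on the log2 scale within the lineage. In the D21 NPC library they made up 8.33%, 16.2% and 20.6% of the lineage, each within the range of the neonatal libraries. These falls thus rest on the lone D56 NPC library, with 0, 1 and 6 of 836 cells. The 3 erythroid stages gave no call. The F-test over ages called 5 of 10 stages in 8 libraries, 3 without either D3 library, and 0 without D56 replicate 2, which leaves no library of that age.

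Hepatocytes made up 4.93% ± 2.09, 3.16% ± 2.47 and 4.06% ± 3.53 of all cells at D1, D3 and D7 (SD, n = 2 each), shares set in part by mixing the fractions by cell number. They made up 79.2% and 97.2% of the H libraries and 0.0336% and 15.7% of the NPC libraries at D21 and D56. Over all cells, 7 of 29 types differed between ages (edgeR): Pro-erythroblast, imNP, iNP, Pro-B, Erythroblast, Large Pre-B and Erythrocyte. The count was 20 without the H libraries, and leaving out single libraries gave 1 to 14: it was 1 without either library of D3 or of D7, 4 without D1 replicate 2, and 14 without either library of D21.

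On average over ages, libraries of the same age were closer in non-hepatocyte composition than libraries in other pairings, but the D21 libraries were not. The mean Bray-Curtis distance within ages was 0.386, against 0.564 over all ways to pair the 10 libraries, and 17 pairings were as close (exact one-sided permutation p = 0.0180). The pairings include those that join neonatal with later libraries, whose distances were all at least 0.559, against at most 0.410 between neonatal libraries. The p-value can therefore reflect the split of neonatal from later libraries, which follows the protocol, and does not by itself show closeness within an age. The distance was 0.251 at D1, 0.247 at D3, 0.206 at D7, 0.394 at D56 and 0.833 between the D21 libraries. The D21 H library lay at 0.379 from the D56 H library, and the D21 NPC library at 0.501 from the D56 NPC library. Over all cells the exact p was 0.114. Among the 6 neonatal libraries the real pairing was the closest of 15, so that p = 0.0667 was the smallest this exact permutation test can give.

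Cells of several types carried fewer UMIs at D56. The log2 difference in library medians of D56 against D1 was -2.77 ± 0.55 in NK cells (SE, adjusted p = 0.000959), -2.33 ± 0.57 in monocytes (adjusted p = 0.00319), -1.67 ± 0.51 in EC, -1.59 ± 0.58 in mNP and -1.50 ± 0.56 in B, and these 5 contrasts passed (limma). Except in EC, the D56 H library held too few cells of these types for a median, so D56 is the lone NPC library, assumed to vary like the other ages. The F-test over ages called NK and monocytes, 2 of 7 types (limma, adjusted p = 0.0197 and 0.0431). Leaving out single libraries gave 0 to 6 calls, with 0 without D1 replicate 1 or D1 replicate 2, 1 without either D3 library, 3 without D56 replicate 1, 5 without D7 replicate 1, and 6 without D7 replicate 2 or D21 replicate 1. Same-numbered neonatal libraries deviated together, with replicate 1 higher in 14, 13 and 14 of 15 types at D1, D3 and D7. With the replicate number as a block 7 of 7 types were called (limma), though at D21 and D56 the number marks the fraction. In the neonatal libraries alone, a choice made after the data were seen, Kupffer was called without the block (limma adjusted p = 0.0318), and Kupffer and NK with it (adjusted p = 2.16e-05 and 0.0472). Without D21 replicate 2 or D56 replicate 2 only 3 and 2 types could be tested, NK and monocytes not among them, and 0 were called. Without both D56 libraries 0 types were called. In Kupffer cells the medians were 9070 and 4709.5 UMIs at D7, against 1913 to 3168.5 in the 4 libraries of D1 and D3, a log2 difference of D7 against D3 of 1.54 ± 0.56 (adjusted p = 0.0981), and 1.54 ± 0.49 (limma adjusted p = 0.0337) with non-hepatocytes of D21 and D56 taken from the NPC libraries only, a choice made after the data were seen. For genes detected at matched UMI counts only EC could be tested (0 called by limma, adjusted p = 0.0974, 0 at an unadjusted p under 0.05), with medians from 1651 to 1924 genes. Its single contrast of D56 with D21 gave a log2 difference of -0.17 ± 0.045, and -0.13 ± 0.036 with EC of D21 and D56 taken from the NPC libraries only. With the replicate number as a block it was -0.15 ± 0.039. Deviations of same-numbered neonatal libraries in this measure correlated at 0.721, 0.415 and 0.645, with replicate 1 higher in 3, 4 and 4 of 5 types at D1, D3 and D7. So few types cannot show whether these libraries deviated together. D56 was the lone NPC library here, so no call is drawn from this contrast. For the mitochondrial share, replicate 1 was higher in 14, 10 and 15 of 15 types at D1, D3 and D7. With the replicate number as a block EC was called (limma adjusted p = 0.0105), though at D21 and D56 the number marks the fraction. Without the block the mitochondrial share differed in 0 of 7 types (limma), with 1 at an unadjusted p under 0.05. It gave 4 calls without D1 replicate 1 and 3 without D1 replicate 2.

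The authors kept between 78.3% and 96.0% of the deposited barcodes in the neonatal libraries. In the D21 H library they kept 16.1% of 7920 barcodes (95% Wilson interval 15.3% to 16.9%), in the D21 NPC library 55.4%, in the D56 H library 85.1% and in the D56 NPC library 96.4%. The mean over D21 and D56 libraries was 63.3%, against 91.1% over neonatal ones, a difference of -27.8 percentage points (exact two-sided permutation p = 0.0619, 210 splits). The difference was -12.1 points without the D21 H library (p = 0.202, exact). Of the 10 fits without 1 library it passed in 2, without D1 replicate 1 (p = 0.0476, exact) and without D56 replicate 2 (p = 0.0238, exact). Hepatocytes kept in the D21 H library had a median mitochondrial share of 8.18%, against 2.56% in the D56 H library.

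**Figure D3:**
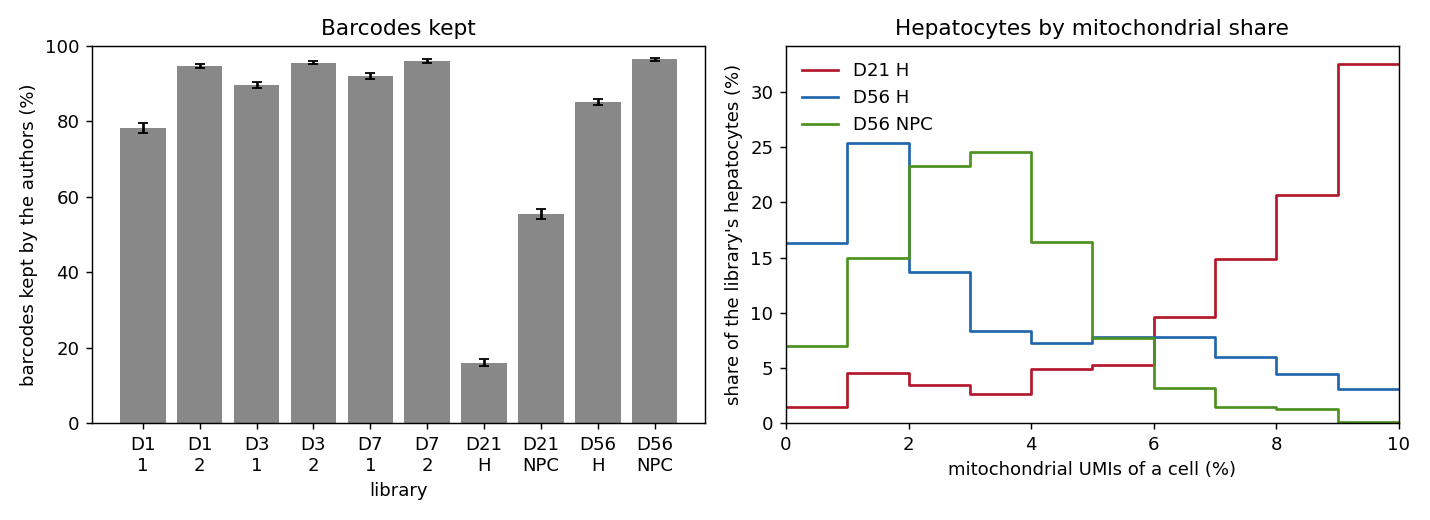
Left, bars give the percentage of barcodes kept by the authors (vertical axis) in each library (horizontal axis), with 95% Wilson intervals. Right, lines give the share of a library's hepatocytes (%, vertical axis) by mitochondrial percentage in steps of 1 point (horizontal axis); in the D21 H library 53.2% of hepatocytes lie from 8% to 10%, against 7.55% in the D56 H library.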

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

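All tests in this part were chosen after the results they bear on had been seen. In the libraries of D1, D3 and D7, 6 of 1425 hepatocytes carried the label Hep-D21, more than the limit of 3 cells for a count of 0, which is not an expected number of mislabelled cells, while 0 hepatocytes of D21 and D56 carried the label Hep-neonatal. These labels entered no comparison, since the hepatocyte labels were merged.

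The D21 H library kept 16.1% of its barcodes. Its hepatocytes increased in number towards the mitochondrial limit: those from 9% to 10% outnumbered those from 7% to 8% by a ratio of 2.19 (exact 95% interval 1.80 to 2.67), against 0.513 in the D56 H library. A mitochondrial limit of 10% that removed a larger tail of barcodes is a candidate explanation. The UMI minimum of 500 seen over all libraries is argued against, since the lowest kept cell there had 825 UMIs. A limit set per library stays open, as the lower quartile of its hepatocytes lay at 902 UMIs. A raised lowest cell was not particular to this library. In the D56 H library, where 85.1% of barcodes were kept, it was 805 UMIs and the lower quartile of hepatocytes 1244 UMIs. Age stays open and untested, as each fraction was measured once; the removed barcodes have no values here.

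The D56 NPC library had fewer UMIs per cell than the D7 libraries in 10 of 10 non-hepatocyte types with a median in it and in both D7 libraries. The log2 shifts had a median of -1.70 and an SD of 0.35, from -2.13 in EC to -0.95 in pDC, and over the 14 types with a median in at least 1 D7 library the median was -1.61 and the SD 0.47, with Meso at -0.28. A lower depth of the whole library may account for part of the shift, though not for the spread between types. Age alone cannot be told apart from it. The same types in the D56 NPC and H libraries, of 1 age, differed by -1.15 on the log2 scale in EC (interval -1.34 to -1.07), -0.37 in hepatocytes and 0.68 in cDC2; this test was first written for EC alone, where the difference would have counted against age, and was widened to all 3 types present in both after the values were seen. The fractions can hold different cells of a type, which keeps it open.

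Dcn+ Mac made up 220 cells in D7 replicate 1 and 49 in D7 replicate 2. Random doublets of a macrophage or monocyte with a Fibroblast, HSC or Meso cell are argued against as the source of all of them in replicate 1, since at most 121 such pairs would arise there even if every droplet held a pair of cells. They are not excluded in D7 replicate 2 (49 cells, at most 144 pairs) or D3 replicate 2 (40 cells, at most 53.8 pairs). Pairs that never came apart may still account for them: the median of 16002 UMIs was 1.20 times the sum of the Kupffer and Fibroblast medians in that library, which a large single cell could give as well. In D7 replicate 2 the ratio was 0.990. Age stays open, with both D7 libraries above the D1 and D3 libraries.

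For the types that differed between later and neonatal libraries, a fit of 2 groups called 16 types. Among 100 of the 210 splits of the libraries into 6 and 4, 1 split, the real one, gave as many, and the highest of the others gave 1. This excludes chance only if single libraries can be exchanged between ages. Of the 10 ways to choose 2 of the 5 ages, D21 with D56 gave 16 types and the highest of the others gave 2; 10 ways are too few for a share under 0.05. The real split also follows the dissociation protocol.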

How the results depend on the processing

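The alternatives without H libraries, with fractions summed, matched or neonatal only, and without D21 or D56, were chosen after seeing the data. So was the contrast of D7 with D1 in the neonatal fit. In the matched setting each type at D21 and D56 came from a single fraction, while the neonatal libraries stayed mixed. The cause of a change was not tested unless stated. Types called over all cells numbered 7, and 16 with TMM factors, 15 with DESeq2, 12 with limma, 20 without H libraries and 20 with fractions summed; single libraries left out gave 1 to 14. For non-hepatocytes limma gave 11 in place of 18, and single libraries left out gave 10 to 19. D21 against D7 gave 0 calls with TMM factors and 2 without erythroid cells in place of 4 (0 to 8 by library left out). D56 against D21 gave 2 with limma in place of 8 (0 to 14), and D56 against D1 gave 7 to 19. Among neonatal ages DESeq2 gave 5 in place of 0 (0 to 5), and for D7 against D1 DESeq2 gave 7 and limma 5 in place of 0 (0 to 6). The later against neonatal count stayed within 12 to 19 in all settings.

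UMIs per cell gave 2 calls, 6 with means, 5 with fractions matched, 6 without D21, 0 without D56 and 1 with neonatal libraries only (0 to 6, with only 3 and 2 types testable without D21 or D56 replicate 2). Genes gave 3 of 4 types with a window of 0.5 to 2, which admits more types. This window matches UMIs less closely, so the lower UMI counts of the D56 NPC library can enter these calls. The mitochondrial share gave 0 to 4, and the stages 0 to 6. Composition distance gave an exact p of 0.114 over all cells and 0.0667 for neonatal libraries. Barcodes kept gave differences from -38.9 to -12.1 points. A minimum of 100 cells per median gave no value for UMIs, genes or mitochondrial share, and genes gave none without D1 replicate 2 or D56 replicate 2.

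The replicate number marks the fraction at D21 and D56. Among neonatal ages the composition deviations of same-numbered libraries correlated at 0.444 (D1 and D3), -0.0185 (D1 and D7) and -0.00812 (D3 and D7). The numbers thus gave no pairing in composition that included D7, though the D1 and D3 libraries deviated together in part. With the replicate number as a block, 7 types were called for UMIs and 1 for the mitochondrial share; counts over composition stayed within 1.5 times.

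For later against neonatal log2 changes, Kupffer (0.29) became -1.27 with TMM factors, -0.40 with limma, -0.081 with the block, -1.91 without H libraries, -1.15 with fractions summed and -0.35 without D21 (-1.50 to 0.75 by library left out). HSC (1.19) became -0.46 with TMM factors, -1.87 without H libraries and -0.89 with fractions summed (-0.78 to 1.87). Dcn+ Mac (1.97) became -2.76 and -0.81 in the last 2 settings (-0.75 to 2.62), and aDC ranged from -1.04 to 3.09 by library left out.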

Other observations

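The NPC libraries of D21 and D56 differed in which cells they held, with 1 library each and no replicate check. Of non-hepatocytes, T and NK made up 37.0% and 24.7% at D21, against 22.0% and 5.85% at D56. EC made up 2.29% (68 of 2971 cells) at D21 and 43.1% (3387 of 7851 cells) at D56. Yet EC made up 48.9% of the 264 non-hepatocytes in the D21 H library (exact 95% interval 42.7% to 55.1%). Cholangiocytes, which line the bile ducts, numbered 1 of 2971 cells at D21 and 108 of 7851 cells at D56. pDC made up 6.33% at D21 and 3.29% at D56, against 0.541% ± 0.357 in neonatal libraries (SD, n = 6). cDC2 made up 15.9% of the 151 non-hepatocytes in the D56 H library, against 3.29% in the NPC library.

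Kupffer cells made up 5.21% ± 0.438 of non-hepatocytes at D1, 8.66% ± 0.522 at D3 and 11.6% ± 0.816 at D7 (SD, n = 2 each), with both D7 libraries above the D1 and D3 libraries. The F-test over these ages did not pass (edgeR adjusted p = 0.209). The median mitochondrial share of EC was 5.37% in the D21 H library and 2.73% in the D21 NPC library, against 1.02% to 1.69% in neonatal libraries.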
